A study of Arabidopsis thaliana with 6 samples.

How the data were processed

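The libraries were made from nuclei of F1 endosperm of Arabidopsis thaliana, collected 4 days after pollination and purified by INTACT, a method that captures nuclei carrying a tagged envelope protein. The parents were the Landsberg erecta accession (Ler, written L) and a Columbia-0 line that carries the INTACT tag and is called TEmob (written Cm). Per the labels' protocols, TEmob goes back to seeds germinated on α-amanitin and 40 µM zebularine, a DNA methylation inhibitor, and then kept at 37 °C. It passed through a haploid stage by a cross to a centromere histone mutant and was made diploid again with colchicine. The cross Cm x L had TEmob as the mother and Ler as the father. The cross L x Cm had the Ler pistillata mutant, which lacks stamens, as the mother and TEmob as the father. Each cross had 3 libraries, for 6 libraries in all. The labels number them 1 to 3 and do not say whether they came from separate plants or pools, so p-values measure the spread between these samples, which may be technical. Endosperm of the untreated Columbia line was not analysed here, so the comparison is between the directions of the cross and not between TEmob and its parent line.

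The authors extracted RNA from the purified nuclei with the mirVana kit, selected poly(A) RNA and built libraries with an NEBNext Ultra II RNA kit, per the labels' protocols. Reads were aligned with TopHat2 version 2.1.0, and the genome build was TAIR10, per the submitters' processing notes. The counting tool, the counting rules and the use of strand are not given in the sources used here. The deposited table holds RPKM values, read numbers scaled by gene length and library total by the authors, as its name states, for 33602 loci in 6 columns. Each column name gives Columbia and Ler in one order of cross and one replicate number, without the tag that marks TEmob. Columns were matched to the labels by parent order and replicate number, because every sample of the series is a TEmob cross. On that basis 0 columns were left unmapped. RPKM divides by a library total and carries no correction between libraries beyond that, so a change in a few very abundant transcripts shifts all other values.

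Depth was recovered from the low values. A gene's RPKM is a whole multiple of what 1 read is worth for its length, and the lengths of pseudogenes in the annotation were used to find that step. The recovered totals were 29.2, 23.6 and 22.2 M reads in Cm x L replicates 1 to 3, and 27.2, 21.7 and 21.2 M in L x Cm replicates 1 to 3. The fit was examined on pseudogenes with few reads, 724 to 2760 of them per library. Between 99.7% and 99.9% of these then held whole numbers of reads within 0.02. The step was chosen for a high share, so this share is not an independent test of it. On an exon length of 1 kb, 1 read was worth 0.0342 to 0.0471 RPKM and 3 reads 0.103 to 0.141 RPKM, which limits counting error only. All 133 chloroplast and 146 mitochondrial genes were listed at 0 in the 6 libraries, so organelle transcripts could not be compared and no rescaling without them was made.

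Locus names, classes, chromosome numbers and exon lengths were taken from the RefSeq annotation of TAIR10.1, to which 32823 of the 33602 loci matched, 26700 of them protein coding. Because this release differs in name from the authors' build, no coordinates are printed. The annotation has no class for transposable element genes, and the 3911 loci it calls pseudogenes were taken in their place. Gene lists were written from general knowledge before the data were examined. Of their 191 loci, 172 carried the same symbol in the annotation, 16 had only a locus name and 3 had another name. The locus number of UCL1 was wrong in the list and was replaced through its symbol, as the rule written beforehand allowed. A list of ribosomal proteins chosen by symbol also took resistance genes and plastid genes and was not used.

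Values were analysed as log2(RPKM + 1). Loci with a mean of at least 1 RPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3, with a moderated test with an intensity trend, 2-sided, with cross direction as the only term and Benjamini-Hochberg adjustment at 0.05. Differences are Cm x L minus L x Cm. A fold given with them is on the log2(RPKM + 1) scale and understates the change of low genes. An exact test of 3 against 3 libraries cannot give a p below 0.10, so adjusted p-values come from limma throughout. Lists with at least 3 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with a correlation estimated from the data; limma's fry tested whether members moved on balance one way, without comparing them with other genes. There were 17 such lists. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the values and drew the figures.

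The fit was tested on simulated data with the spread of the 26620 real loci and 200 changed genes. It called 6% of the 100 genes changed by 1 on the log2 scale and 45% of the 100 changed by 2, with 1 false call among 52. With so few changed genes, a call needed a smaller unadjusted p than in the real data, where 6662 loci were called. These shares therefore do not give the power of the real fit. A simulated list of raised genes was called by camera and 0 of the unchanged lists were. Simulated errors were independent between genes, so false calls of lists whose members move together were not tested.

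Named genes followed a rule set before the data were examined. It took the 10 largest differences in each direction among called genes whose crosses did not overlap, up to 4 called members of each list by size (or the 2 most abundant members where none was called), and MEA, FIS2, FWA, PHE1, AGL62, IKU2, MINI3, PI, RANGAP1 and ERECTA. A gene that overlaps another locus, or has a close copy, is uncertain because reads could be assigned to either. Among the named genes this applies by overlap to AT3G16070, LBD42, SDC, FIS2, FWA, IKU2, MSI1, FIE, SHH1, CDKB1;1, CDKB2;1, CDKB2;2, YUC11, RANGAP1 and ONSEN-1, to AT3G31068 and AT1G43624 because they had no match in the annotation, and by close copies to the ATCOPIA78 elements, VGD1 and VGDH1, and the seed storage albumins.

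Alternatives set beforehand were pseudocounts of 0.1 and 5, no filter on level and a mean of at least 5 RPKM, median-ratio scaling, quantile normalization, moderation without the trend or with a robust trend, the replicate number as a block, a minimum difference of 2-fold, and each library left out in turn. Alternatives chosen after the data were seen were a mean of at least 20 RPKM, subtraction of each library's median pseudogene value, and the pollen or the seed coat marker score as a covariate.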

Results

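Poly(A) RNA of purified endosperm nuclei was compared between the 2 directions of a cross between TEmob, a Columbia line in which transposon mobilization had been induced chemically, and Ler. There were 3 libraries of Cm x L (TEmob mother) and 3 of L x Cm (Ler mother), with 21.2 to 29.2 M reads each. Endosperm receives a larger genome dose from the mother than from the father, so the comparison asks which transcripts depend on the direction of the cross. Direction also sets which accession contributed the larger dose and the share of reads that match the Columbia reference exactly. The INTACT tag came from the mother in Cm x L and from the father in L x Cm, so its dose and the purification are confounded with direction. Across the tested loci, libraries of the same cross correlated at 0.903 to 0.977 on the log2 scale and libraries of different crosses at 0.831 to 0.883.

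AT1G54040, the epithiospecifier protein of glucosinolate breakdown, known to be functional in Ler and not in Columbia, had 1.40 ± 1.32 RPKM in Cm x L and 91.1 ± 30.7 in L x Cm (mean ± SD, n = 3 per cross; log2 difference −5.40, SE 0.47, adjusted p = 0.0042). The transcription factor gene LBD8 had 17.7 ± 18.0 against 245 ± 92.8 RPKM (−4.07, adjusted p = 0.0073). AT4G39130, a dehydrin family gene, had 2.46 ± 0.96 against 69.2 ± 23.8 RPKM. The pectin methylesterase gene VGDH1 had 27.3 ± 33.0 against 355 ± 273 RPKM. Like the pollen markers AGP23 and VGD1, VGDH1 was highest in replicate 2 of each cross (65.4 and 668 RPKM). The tRNA loci AT1G01870 and AT1G03640 were listed at 0 in the 3 Cm x L libraries. In L x Cm, AT1G01870 had 27.2, 31.6 and 9.04 RPKM and AT1G03640 had 31.2, 8.21 and 15.5 RPKM. Another tRNA locus, AT1G54670, had 0.581 RPKM in 1 Cm x L library and 26.1 ± 7.85 RPKM in L x Cm. These loci are shorter than 1 kb, so 1 read there is worth more RPKM than the value given for 1 kb. Whether the tRNA loci have close copies that share reads was not examined. The pseudogenes AT4G06477 (43.1 ± 24.1 against 1008 ± 341 RPKM) and AT4G06716 (1.79 ± 2.77 against 41.7 ± 10.6 RPKM) and the locus AT1G43624 (0.97 ± 0.86 against 51.5 ± 13.7 RPKM) completed the 10 largest differences in this direction.

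In the other direction, TGG2, a myrosinase that cleaves glucosinolates, had 61.8 ± 29.0 RPKM in Cm x L and 7.36 ± 3.24 in L x Cm (log2 difference 2.89, SE 0.40, adjusted p = 0.0066). The transcribed pseudogene AT3G32377 had 19.5 ± 2.51 against 0.54 ± 0.48 RPKM (3.78, adjusted p = 0.0042), and AT3G16070 had 40.0 ± 30.4 against 1.66 ± 0.13 RPKM (3.48, adjusted p = 0.015). NRT2.7, a nitrate transporter gene of seeds, had 147 ± 102 against 14.6 ± 1.77 RPKM (2.92, adjusted p = 0.012). The neighbouring microRNA locus MIR398c had nearly the same values in every library (144 ± 100 against 14.2 ± 1.51 RPKM), so the reads behind the pair could not be told apart. AIG2L had 20.5 ± 7.43 against 2.33 ± 1.84 RPKM. AT5G45095 had 11.5 ± 4.74 against 0.51 ± 0.18 RPKM and AT3G31068 had 19.6 ± 15.3 against 1.35 ± 1.72 RPKM. The transcription factor gene LBD42 (160 ± 104 against 21.7 ± 15.2 RPKM) and AT5G49410 (52.7 ± 42.9 against 4.74 ± 2.12 RPKM) were also higher. Cm x L replicate 3 held 41.7 RPKM of LBD42 and 7.18 RPKM of AT5G49410. Of these 20 loci, AT3G16070, AT3G31068, AT5G49410, LBD42 and VGDH1 lost the call in at least 1 of the 6 fits without 1 library. The others kept it in all 6.

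By limma, 1792 of 26620 tested loci were higher in Cm x L and 4870 were lower, and 11050 had an unadjusted p under 0.05. Of the called loci, 660 and 4480 differed by at least 2-fold. The libraries of the crosses did not overlap at 45.5% of tested loci, where chance gives 10%. The balance of calls changed with expression level. Of the 8503 loci with a mean of at least 20 RPKM, 1198 were higher and 570 lower in Cm x L, with a median log2 difference of 0.14. Of the 18117 loci below that level, 594 were higher and 4300 lower. Loci with a mean under 5 RPKM made up 64.5% of the lower calls and 2.46% of the higher calls. The share of calls that were lower was 73.1% as deposited and 45.7% after quantile normalization, which moved the median log2 difference of all tested loci from −0.22 to 0.04. Libraries differed at this low end: 5036, 1005 and 10084 loci were listed at 0 in Cm x L replicates 1 to 3, and 1270, 2137 and 3636 in L x Cm replicates 1 to 3. Leaving out 1 library moved a count by over 1.5 times in 4 cases. There were 369 higher and 1291 lower loci without Cm x L replicate 1 and 878 higher without Cm x L replicate 2. There were 797 higher and 1732 lower without L x Cm replicate 1, and 526 higher and 1779 lower without L x Cm replicate 2.

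**Figure D1:**
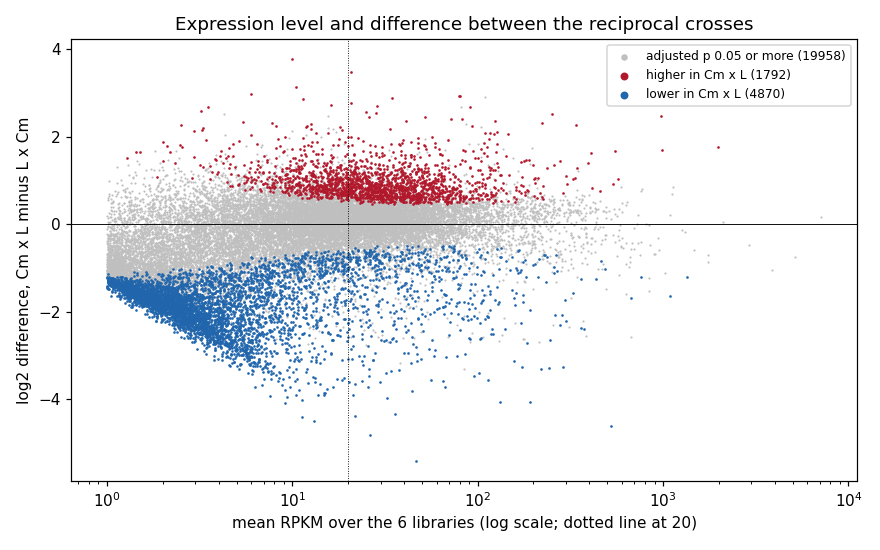
Log2 difference between the crosses (Cm x L minus L x Cm, vertical) against the mean RPKM over the 6 libraries (horizontal, log scale) for 26620 loci, with the 1792 loci higher in Cm x L in red, the 4870 lower in blue and the others in grey. Lower calls crowd at low expression, and among loci to the right of the dotted line at 20 RPKM there were 1198 higher and 570 lower calls.

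Imprinted genes, whose expression depends on the parent that transmitted them, went in both directions. The values sum the reads of both parental alleles, so a difference between the crosses is not a measure of imprinting. Direction also changes which accession supplied the allele from each parent, and how well its reads match the reference. Of 13 maternally expressed genes, 4 were higher in Cm x L and 0 lower, with the same count when adjusted over the list alone. ALN, which encodes allantoinase, had 67.8 ± 5.55 RPKM in Cm x L and 22.4 ± 1.85 in L x Cm (log2 difference 1.56, SE 0.15, adjusted p = 0.0047). SDC, an F-box gene silenced by DNA methylation in most tissues, had 279 ± 65.4 against 98.9 ± 9.04 RPKM (1.47, adjusted p = 0.0070). FIS2 had 36.1 ± 6.03 against 23.1 ± 1.44 RPKM and MYB3R2 had 32.5 ± 2.21 against 22.5 ± 2.03 RPKM. FWA (107 ± 16 against 78.5 ± 6.16 RPKM, adjusted p = 0.088) and MEA (7.48 ± 2.74 against 10.5 ± 5.53 RPKM, adjusted p = 0.54) did not pass. Of 12 tested paternally expressed genes, 1 was higher and 3 were lower, or 4 lower when adjusted over the list alone. HDG3, a homeodomain gene, was higher (148 ± 35.8 against 64.7 ± 3.60 RPKM, log2 difference 1.15, adjusted p = 0.011). PEG9 (33.7 ± 24.4 against 143 ± 63.6 RPKM), ADM (1.94 ± 1.27 against 7.82 ± 1.96 RPKM) and TAR1 (14.9 ± 1.99 against 29.1 ± 10.7 RPKM) were lower. ADM lay at a level where lower calls prevailed across all loci. PHE1 did not pass (46.5 ± 5.56 against 53.3 ± 0.61 RPKM, adjusted p = 0.34). By camera neither list differed from other genes (adjusted p = 0.075 and 0.50, and 0.54 and 0.79 with an estimated correlation). The maternally expressed list was called as higher without Cm x L replicate 1 or 2 (adjusted p = 0.038 and 0.046), with no filter on level (adjusted p = 0.038) and with the seed coat score as a covariate (adjusted p = 0.029). With no filter the median of the list stayed at 0.029, while that of all tested loci moved from −0.22 to −0.28. Such a call relative to other loci does not by itself mean that the list rose. The adjusted p of the list ran from 0.029 to 0.49 over 19 alternatives, with medians from −0.21 to 0.47. The calls of ALN, SDC and HDG3 held in each of the 6 fits without 1 library, whereas those of PEG9 and ADM held in 3, that of FIS2 in 2, that of TAR1 in 1 and that of MYB3R2 in 0.

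Among 16 regulators of endosperm development, 3 were lower in Cm x L and 2 higher, or 6 lower and 2 higher when adjusted over the list alone. MINI3, a WRKY transcription factor gene of the HAIKU seed size pathway, had 23.2 ± 17.5 RPKM in Cm x L and 117 ± 10.7 in L x Cm (log2 difference −2.52, SE 0.42, adjusted p = 0.0089). IKU2, a receptor kinase gene of the same pathway, had 1.42 ± 1.39 against 5.36 ± 1.52 RPKM, and IPT8, a cytokinin synthesis gene, had 6.41 ± 2.76 against 27.3 ± 13.4 RPKM. HDG3, given above, and the sugar transporter gene SWEET15 were higher, the latter at 55.3 ± 33.4 against 12.4 ± 1.88 RPKM. AGL62, whose loss brings early cellularization of the endosperm, did not pass (20.5 ± 15.8 against 46.9 ± 16.0 RPKM, adjusted p = 0.066). Its values were 10.2, 12.6 and 38.7 RPKM in Cm x L replicates 1 to 3. Without replicate 3 it was called (adjusted p = 0.0032, in a range of 0.0032 to 0.20 over the alternatives). Of 23 type I MADS-box genes, 4 were lower (AGL48, AGL80, AGL95 and AGL100) and AGL28, chosen after its values were seen, was higher (11.7 ± 1.39 against 5.32 ± 2.44 RPKM). AGL48 had 3.58 ± 0.94 against 14.9 ± 3.56 RPKM and AGL80 had 2.68 ± 0.96 against 11.3 ± 3.05 RPKM. AGL95 had 10.1 ± 8.00 against 30.6 ± 0.76 RPKM and AGL100 had 0.35 ± 0.60 against 3.37 ± 2.19 RPKM. Of 6 auxin synthesis genes, YUC11 (3.41 ± 2.93 against 13.7 ± 3.09 RPKM) and TAR1 were lower. IKU2, IPT8, AGL48, AGL80, AGL100 and YUC11 lay at levels where lower calls prevailed across all loci. Adjusted over the list alone, the counts of the MADS-box and auxin lists were the same. The calls of MINI3, AGL48 and AGL80 held in each of the 6 fits without 1 library, that of IPT8 in 4, that of YUC11 in 3, that of AGL100 in 2 and those of IKU2, SWEET15, AGL95, AGL28 and TAR1 in 1. None of these 3 lists differed from other genes by camera (adjusted p = 0.73, 0.50 and 0.47). The MADS-box list was called among loci with a mean of at least 20 RPKM (adjusted p = 0.019; 0.019 to 0.88 over 19 alternatives).

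By camera, 8 of the 17 lists differed from other genes, and 0 did with a correlation estimated from the data. Camera sets a list against the other tested loci. The median log2 difference of all tested loci was −0.22, so an upward call is relative to that shift. In the Polycomb repressive complex 2, which deposits repressive histone H3 methylation, 4 of 8 subunit genes were higher and 0 lower (camera adjusted p = 0.035; adjusted p = 0.38 with an estimated correlation). MSI1 had 50.4 ± 2.23 against 28.4 ± 1.21 RPKM (log2 difference 0.80, SE 0.14, adjusted p = 0.0099). FIE had 125 ± 13.0 against 71.7 ± 8.62 RPKM, SWN had 81.7 ± 10.4 against 47.3 ± 7.47 RPKM, and FIS2 is given above. Of 23 genes of DNA methylation, its removal and the RNA-directed pathway, 4 were higher and 1 lower (camera adjusted p = 0.0068; adjusted p = 0.38 with an estimated correlation). AGO9, an Argonaute protein, had 55.4 ± 9.80 against 22.8 ± 4.92 RPKM. SHH1, which recruits RNA polymerase IV, had 39.8 ± 6.17 against 18.4 ± 2.03 RPKM. AGO4 (67.5 ± 14.2 against 38.3 ± 8.02 RPKM), chosen after its values were seen, and SDC, a target of this pathway and not a part of it, were the others. The demethylase gene DML3 was lower, at 9.55 ± 2.83 against 27.4 ± 4.39 RPKM. Of 14 cell cycle genes, 4 were higher and 0 lower (camera adjusted p = 3.4e-04; adjusted p = 0.38 with an estimated correlation). They were the mitotic kinases CDKB2;1 (30.1 ± 13.1 against 12.9 ± 1.78 RPKM), CDKB2;2 (32.6 ± 7.94 against 15.3 ± 4.95 RPKM) and CDKB1;1 (39.8 ± 8.38 against 21.8 ± 1.32 RPKM), and PCNA1 (46.5 ± 3.75 against 31.5 ± 2.59 RPKM). The cell cycle genes of Cm x L replicate 3 lay near the level of L x Cm, with a mean log2 level of 4.05 against 4.84 and 4.80 in replicates 1 and 2 and 4.15, 3.80 and 3.80 in L x Cm, and without that library the list median moved from 0.54 to 0.82. CDKB2;1 had 16.0 RPKM there. Of 17 histone genes, HTA2 (82.1 ± 3.28 against 53.8 ± 7.60 RPKM) and HTA7 (138 ± 34.6 against 83.6 ± 3.99 RPKM) were higher. HTA11, an H2A.Z gene, was lower, at 820 ± 173 against 1872 ± 252 RPKM. Adjusted over the list alone, 0 histone genes passed by limma, of 7 with an unadjusted p under 0.05, and the counts of the Polycomb, DNA methylation and cell cycle lists were the same. The calls of MSI1, AGO9, SHH1 and DML3 held in each of the 6 fits without 1 library and those of FIE and SWN in 3. Those of AGO4, CDKB2;2, CDKB1;1 and HTA2 held in 2 and those of CDKB2;1, PCNA1, HTA7 and HTA11 in 1. The histone list was called as higher (camera adjusted p = 0.022; adjusted p = 0.54 with an estimated correlation). The Polycomb call was lost without Cm x L replicate 3, L x Cm replicate 1 or L x Cm replicate 2 (adjusted p = 0.066, 0.051 and 0.059) and after quantile normalization, with a mean of at least 5 RPKM, after floor subtraction and with the pollen score (adjusted p = 0.082, 0.094, 0.073 and 0.13; 0.016 to 0.13 over 19 alternatives, with medians from 0.32 to 0.78). The call of DNA methylation genes was lost with a mean of at least 5 RPKM (adjusted p = 0.11; 0.0014 to 0.11 over 19 alternatives, with medians from 0.15 to 0.80) and that of cell cycle genes with at least 20 (adjusted p = 0.053; 6.9e-06 to 0.053 over 19 alternatives, with medians from 0.48 to 1.048). The histone call was lost without Cm x L replicate 3, where the median moved from 0.24 to −0.03, without L x Cm replicate 2, where it was 0.15, and after quantile normalization (adjusted p = 0.13, 0.059 and 0.28; 0.0038 to 0.74 over 19 alternatives, with medians from −0.24 to 0.32). It was also lost with a mean of at least 5 or 20 RPKM, after floor subtraction and with the pollen score (adjusted p = 0.19, 0.52, 0.10 and 0.74). By fry, which asks whether members moved on balance one way, adjusted p was 0.0075 for the Polycomb list and 0.047 for the DNA methylation, heat shock, seed storage, embryo and pseudogene lists.

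**Figure D2:**
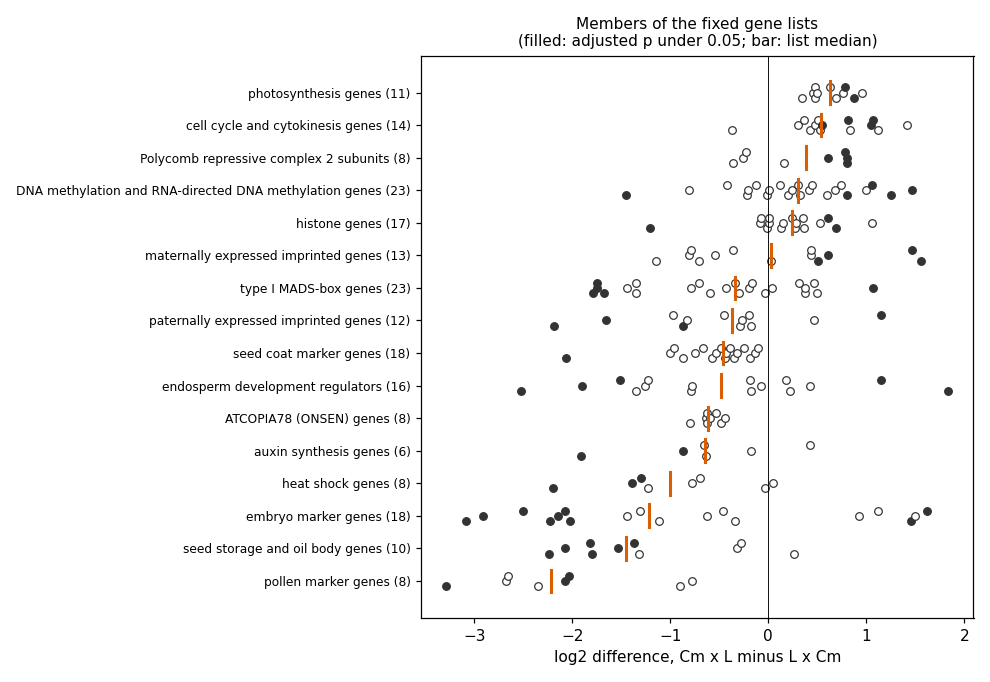
Log2 difference between the crosses (Cm x L minus L x Cm, horizontal) of each tested member of 16 gene lists, with the number of tested members in parentheses; filled points had an adjusted p under 0.05 and the orange bar is the list's median. The medians ran from −2.21 for pollen markers to 0.63 for photosynthesis genes.

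Lists written as markers of tissues other than endosperm were compared as well. Whether their members are also expressed in endosperm was not tested, so a difference need not come from another tissue. Of 18 embryo markers, 7 were lower in Cm x L and 2 higher, or 9 and 4 when adjusted over the list alone. The lower ones included the shoot meristem gene STM (1.39 ± 0.80 against 17.1 ± 6.85 RPKM, log2 difference −2.91, SE 0.37, adjusted p = 0.0058), the organ boundary gene CUC3 (0.38 ± 0.37 against 11.2 ± 6.01 RPKM), WOX9 (2.60 ± 0.80 against 19.9 ± 7.07 RPKM) and the root stem cell gene PLT1 (0.80 ± 0.71 against 7.17 ± 1.98 RPKM). LEC1 (126 ± 48.9 against 44.7 ± 16.5 RPKM) and LEC2 (32.7 ± 13.6 against 10.1 ± 5.22 RPKM), regulators of embryo maturation chosen after their values were seen, were the higher ones. The calls of STM, CUC3, WOX9 and PLT1 held in each of the 6 fits without 1 library, that of LEC2 in 2 and that of LEC1 in 1. The list as a whole did not differ from other genes by camera (adjusted p = 0.21). Its median log2 difference was −1.21 over all members and 1.46 over those with a mean of at least 20 RPKM. Of 10 seed storage and oil body genes, 6 were lower and 0 higher, or 7 lower when adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.54 with an estimated correlation). They included the cruciferins CRA1 (1.85 ± 0.13 against 13.4 ± 6.96 RPKM) and CRU3 (2.60 ± 0.50 against 11.9 ± 4.43 RPKM) and the albumins SESA4 (2.98 ± 1.03 against 15.73 ± 4.52 RPKM) and SESA3 (5.83 ± 1.79 against 23.7 ± 8.92 RPKM). These values, and those of STM, CUC3, WOX9 and PLT1, lay in the range of levels where lower calls prevailed across all loci. The storage list lost its call without Cm x L replicate 3 (adjusted p = 0.087; 0.0040 to 0.087 over 18 alternatives, with medians from −1.87 to −0.84), and the calls of its 4 named genes held in each fit without 1 library.

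Pollen markers had a median log2 difference of −2.21. Of 8 members, 3 were lower and 0 higher, or 6 lower when adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.66 with an estimated correlation). VGD1, a pectin methylesterase of pollen tubes, had 56.6 ± 64.6 RPKM in Cm x L and 428 ± 309 in L x Cm (log2 difference −3.28, SE 0.78, adjusted p = 0.022). TIP1;3 had 0.83 ± 0.72 against 7.16 ± 4.76 RPKM and PPME1 had 3.80 ± 4.54 against 13.8 ± 2.02 RPKM. Both lay at levels where lower calls prevailed across all loci. VGD1 reached 131 RPKM in Cm x L replicate 2 and 781 RPKM in L x Cm replicate 2, the highest library of each cross. The list lost its call without Cm x L replicate 3, L x Cm replicate 2 or L x Cm replicate 3 (adjusted p = 0.13, 0.078 and 0.093; 0.0012 to 0.49 over 19 alternatives, with medians from −3.05 to 0.017). It was also lost with a pseudocount of 0.1 (adjusted p = 0.058) and with its own score as a covariate (adjusted p = 0.49). Of the 6 fits without 1 library, VGD1 and TIP1;3 were called in 3 and PPME1 in 1. Among 18 seed coat markers, TT1 was lower (126 ± 124 against 395 ± 21.8 RPKM, adjusted p = 0.034), but 0 passed when adjusted over the list alone. The list had a median of −0.46 and did not differ by camera (adjusted p = 0.38, and 0.79 with an estimated correlation), and 3 members had an unadjusted p under 0.05. Without Cm x L replicate 3 the seed coat list was called, with a median of −1.02 (adjusted p = 0.0064), and after quantile normalization (adjusted p = 0.037; 0.0064 to 0.98 over 19 alternatives). It was also called with a mean of at least 5 or 20 RPKM and with the pollen score (adjusted p = 0.023, 0.015 and 0.015). Cm x L replicate 3 held 270 RPKM of TT1 against 50.7 and 59.0 RPKM in replicates 1 and 2, and TT1 was called in 1 of the 6 fits without 1 library. All 11 photosynthesis genes had a positive difference. LHCA1 (294 ± 102 against 154 ± 8.49 RPKM) and LHCB5 (236 ± 64.5 against 135 ± 23.9 RPKM) passed over all genes, and 0 when adjusted over the list alone. Without 1 library LHCA1 was called in 1 of the 6 fits and LHCB5 in 0. The photosynthesis list was called (camera adjusted p = 1.9e-04; adjusted p = 0.54 with an estimated correlation), except with the pollen score as a covariate (adjusted p = 0.074; 4.2e-06 to 0.074 over 19 alternatives, with medians from 0.32 to 0.78). Its median moved from 0.63 to 0.37 without Cm x L replicate 3, the library with the highest mean log2 level of these genes (8.22 against 7.49 and 7.69 in replicates 1 and 2). LHCA1 had 412 RPKM there against 224 and 248 RPKM.

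**Figure D3:**
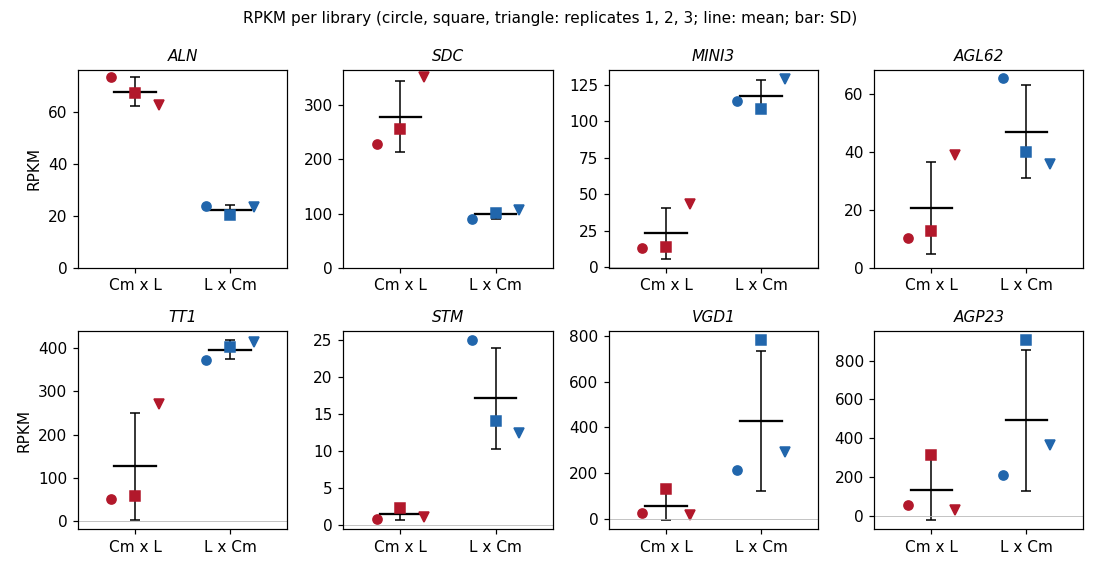
RPKM (vertical, linear) in each library of Cm x L (red) and L x Cm (blue) for 8 genes; circles, squares and triangles are replicates 1, 2 and 3, the line is the mean of 3 libraries and the bar its SD. ALN and SDC separated the crosses in every library. MINI3, AGL62 and TT1 of Cm x L replicate 3 lay nearer to L x Cm than in replicates 1 and 2, and VGD1 and AGP23 were highest in replicate 2 of each cross.

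Transposon-derived loci were examined because transposon mobilization is the subject of the study. Of 3911 annotated pseudogenes, the class used here in place of transposable element genes, 1208 had a mean of at least 1 RPKM. Of these, 534 were lower in Cm x L and 31 higher, or 736 and 40 when adjusted over the list alone (median log2 difference −1.33, camera adjusted p = 1.8e-15; adjusted p = 0.54 with an estimated correlation). The median depended on the level and scale of the loci. It was −2.97 with a pseudocount of 0.1 and −0.47 with 5, −0.55 with no filter on level, −0.46 and −0.28 with a mean of at least 5 and 20 RPKM, −0.84 with the pollen score and −0.21 after quantile normalization. The list was called as lower in each of the 19 alternatives (adjusted p = 1.6e-20 to 0.019). Lower calls at low levels were not particular to pseudogenes. Of the 3141 loci of any class with a mean under 5 RPKM that were lower in Cm x L, 2408 were protein coding and 488 pseudogenes. No comparison with protein-coding genes of the same level was made, so these counts do not show whether the share of lower calls differed between the classes. AT4G06664 had 0.86 ± 0.95 against 28.6 ± 20.2 RPKM and AT4G06712 had 1.54 ± 0.89 against 40.9 ± 28.2 RPKM. The median pseudogene had 0.0315, 0.589 and 0 RPKM in Cm x L replicates 1 to 3 and 1.35, 0.804 and 0.538 RPKM in L x Cm replicates 1 to 3. None of the 8 tested loci of ATCOPIA78 (ONSEN), a heat-responsive retrotransposon family with near-identical copies, passed by limma, and 0 had an unadjusted p under 0.05 (median log2 difference −0.61). ONSEN-1 had 4.68 ± 2.66 against 7.10 ± 1.97 RPKM (adjusted p = 0.31) and ONSEN-2 had 3.33 ± 1.82 against 6.10 ± 1.58 RPKM (adjusted p = 0.17). By camera the family did not differ from other genes (adjusted p = 0.38; adjusted p = 0.79 with an estimated correlation). With the seed coat score as a covariate it was called as lower (median −1.06, adjusted p = 0.010; 0.010 to 0.88 over 17 alternatives). ONSEN-1 and ONSEN-2 were also called there (adjusted p = 0.026 and 0.028; 0.026 to 0.89 and 0.028 to 0.95 over the alternatives). The median was −0.15 without Cm x L replicate 3, 0.39 after quantile normalization and 0.37 with the pollen score. Of 8 tested heat shock genes, HSP17.6A (1.19 ± 2.06 against 6.93 ± 2.62 RPKM), HSP17.6II (0.32 ± 0.30 against 2.54 ± 1.20 RPKM) and the heat shock factor gene HSFA2 (1.052 ± 0.45 against 4.05 ± 1.11 RPKM) were lower and 0 were higher, or 4 lower when adjusted over the list alone (camera adjusted p = 0.17). HSP17.6A and HSFA2 were called in 2 of the 6 fits without 1 library and HSP17.6II in 1 of the 5 in which it was tested. All of these genes lay at levels where lower calls prevailed across all loci.

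The chromosomes had similar medians, and their ranges over library pairs overlapped. The median log2 difference of tested loci was −0.21, −0.28, −0.20, −0.24 and −0.20 on chromosomes 1 to 5. Over the 9 pairs of libraries from different crosses it ran from −0.33 to −0.06 on chromosome 1, from −0.41 to −0.10 on chromosome 2 and from −0.29 to −0.06 on chromosome 5. Without L x Cm replicate 1 the medians were −0.12, −0.18, −0.12, −0.15 and −0.11. With a mean of at least 20 RPKM they were 0.16, 0.14, 0.13, 0.15 and 0.13. Of the genes tied to the parental stocks, PI and ERECTA did not pass. PI, mutated in the Ler mother, had 1.67 ± 1.11 against 1.59 ± 1.46 RPKM (adjusted p = 0.90), and ERECTA, mutated in Ler, had 1.96 ± 0.50 against 3.39 ± 0.92 RPKM (adjusted p = 0.23). RANGAP1, part of whose sequence the INTACT nuclear tag carries, had 50.6 ± 4.10 against 35.3 ± 2.05 RPKM (log2 difference 0.51, SE 0.15, adjusted p = 0.040). The tag came from the mother in Cm x L and from the father in L x Cm. Whether reads of the tag entered these values was not tested. The call of RANGAP1 held in 1 of the 6 fits without 1 library and in 10 of 19 alternatives (adjusted p = 0.029 to 0.22).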

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

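Settings were fixed before the data were examined except a mean of at least 20 RPKM, floor subtraction and the covariates. Among planned settings with all libraries, loci higher in Cm x L numbered 1242 to 2247, and 660 with at least 2-fold. Over fits without 1 library they ran from 369 to 2289. With a mean of at least 20 RPKM there were 911, and with the pollen score as a covariate 4. Loci lower in Cm x L numbered 1322 with a mean of at least 5 RPKM, 375 with at least 20, 1739 after quantile normalization and 45 with the pollen score. They ran from 1291 to 5263 over fits without 1 library. Fewer loci are tested under the stricter filters. The pollen score separated the crosses (1.95 to 4.65 in Cm x L and 5.02 to 5.83 in L x Cm), so this fit cannot fully tell it apart from cross direction. The median log2 difference of all tested loci was −0.14 there and −0.22 in the reported fit. Why the calls were lost was not tested. The cause of the quantile value was not tested. Of the 6662 calls, 5358 kept their sign and call after floor subtraction, 2912 after quantile normalization and 1655 without Cm x L replicate 1.

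The number of lists called was 8 in the reported fit, 6 to 9 under the planned settings with all libraries, 5 with the pollen score and 10 with the seed coat score; it ran from 5 to 9 without 1 library. Transposable element genes detected, counted as annotated pseudogenes, numbered 2262 at a mean of at least 0.5 RPKM and 137 at 5, which the filter itself sets. Directions of called lists and of named genes turned for the pollen marker genes with their own score as covariate (0.017), ONSEN-1 and ONSEN-2 with that covariate (0.38 and 0.0832), ERECTA after quantile normalization (0.51) and PI with the seed coat score (−0.62). PI ran from −0.33 to 0.53 without 1 library. The median of the called histone list turned to −0.029 without Cm x L replicate 3 and −0.24 with the pollen score. Medians of lists that were not called turned for maternally expressed genes (−0.12 without Cm x L replicate 3, −0.022 without L x Cm replicate 1, −0.21 with the pollen score), ATCOPIA78 genes (0.39 after quantile normalization, 0.37 with the pollen score), embryo markers (1.46 with a mean of at least 20 RPKM) and seed coat markers (0.079 with their own score). The cause was not tested, and none of these 4 genes was called in the reported fit. All 70 called named genes kept their sign wherever tested. Of these, 38, 50 and 61 stayed called without Cm x L replicates 1 to 3, and 39, 35 and 55 without L x Cm replicates 1 to 3. Among other results under the alternatives, named genes gave 1131 values on the same side of the threshold, 294 that lost and 3 that gained a call, and lists 284, 22 and 11.

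The median difference per chromosome depended on which loci entered. On chromosomes 1 to 5 it was 0.051, 0.049, 0.055, 0.045 and 0.069 with a mean of at least 5 RPKM and 0.16, 0.14, 0.13, 0.15 and 0.13 with at least 20, where fewer loci are tested. It was 0.056, 0.028, 0.048, 0.047 and 0.035 after quantile normalization and −0.038, −0.081, −0.034, −0.067 and −0.027 after floor subtraction. It was −0.13, −0.20, −0.12, −0.16 and −0.12 with median-ratio scaling, −0.14, −0.18, −0.13, −0.16 and −0.12 with the pollen score and −0.14, −0.18, −0.14, −0.16 and −0.14 with a pseudocount of 5; the cause was not tested. Without 1 library it ran from −0.25 to −0.12, −0.38 to −0.18, −0.25 to −0.12, −0.28 to −0.15 and −0.24 to −0.11, nearest to 0 on each without L x Cm replicate 1.

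Deviations of same-numbered libraries correlated at 0.081, 0.15 and 0.20, not all above the bound of 0.1 for treating the numbers as pairs. Of the 6 correlations between different numbers, 5 were negative, which deviations that sum to 0 within a cross favour, and L x Cm replicate 1 correlated best with Cm x L replicate 2 (0.12). A batch shared by number is not excluded. With the replicate block 1963 loci were higher and 4887 lower, and 5797 of the 6662 calls of the reported fit were kept. Of the 70 called named genes, 66 stayed called. Depth limits values to about 0.103 to 0.141 RPKM, the worth of 3 reads on 1 kb. In simulation 45% of genes changed by 2 on the log2 scale were called. Without organelle genes no rescaled value could be made, because they were listed at 0.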

Other observations

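All tests here were chosen after the values they bear on had been seen. Gene families were picked by product name after the words of all products had been screened on these values, so they are described without p-values. There are 9 of them, counted among loci with a mean of at least 20 RPKM, of which 1198 of 8503 were higher in Cm x L and 570 lower. Of 37 low-molecular-weight cysteine-rich protein genes, 24 were lower in Cm x L and 1 was higher, with a median log2 difference of −1.25. Of members chosen after their values were seen, LCR12 had 23.8 ± 28.2 RPKM in Cm x L and 203 ± 83.3 in L x Cm, and LCR84 had 260 ± 85.1 against 613 ± 193 RPKM (SD, n = 3). The exception, LCR69, had 1691 ± 997 against 256 ± 34.8 RPKM. Of 36 defensin-like genes 13 were lower and 0 higher (median −1.04), and of 21 homologues of self-incompatibility proteins 10 were lower and 1 higher (median −1.27). Of 53 helicase genes 24 were higher and 0 lower (median 0.48), and of 16 chaperonin genes 6 were higher and 0 lower (median 0.50). Of 286 ribosomal protein genes 32 were higher and 3 lower, and most did not pass (median 0.37).

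The other 3 families had their highest Cm x L and L x Cm averages in replicate 2, as the most abundant pollen markers did. Of 31 inhibitors of invertase and pectin methylesterase 8 were lower, of 12 RALF-like peptide genes 6 and of 15 pectin lyase-like genes 4, and 0 of these were higher. On the log2 scale the inhibitors averaged 4.93, 5.81 and 5.43 in Cm x L replicates 1 to 3 and 6.56, 7.08 and 6.80 in L x Cm replicates 1 to 3. In the same order, the RALF-like genes averaged 4.57, 5.75, 4.08, 6.48, 7.03 and 6.33, and the pectin lyase-like genes 4.29, 5.21, 3.83, 5.44, 6.02 and 5.19. The cysteine-rich family averaged 5.60, 5.41, 5.95, 7.45, 6.89 and 6.92. The medians of the 9 families kept their sign under median-ratio scaling and quantile normalization.

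At low expression, 3141 loci with a mean under 5 RPKM were lower in Cm x L, 2408 of them protein coding. Library depth is argued against, since the deepest Cm x L library had 20413 loci at 1 RPKM or more and the shallowest L x Cm library 25751. Genomic DNA as the whole cause would give an even floor. This was examined over 4748 near-silent loci, chosen as low in Cm x L replicates 1 and 3 and above a cut in Cm x L replicate 2. There the 90th percentile was 15.5 and 27.5 times the 10th in L x Cm replicates 1 and 2 (the 10th was 0 in replicate 3). It was 3.14 times in Cm x L replicate 2, which that cut partly set. The loci were thus uneven in L x Cm, but without an unselected yardstick genomic DNA is not decided. Pollen RNA is not decided, because replicate 2, with the most abundant pollen markers of each cross, lay above replicate 1 at 21.8% of these loci in L x Cm but at 87.5% in Cm x L. The Cm x L share cannot bear on pollen, since replicate 2 had a raised floor there (median pseudogene 0.589 RPKM against 0.0315 in replicate 1). The L x Cm share goes against pollen RNA as the whole cause but rests on a single pair of libraries. A part from depth, a difference in nuclear RNA quality, and a broader low-level transcription in endosperm of a Ler mother stay open and untested. Nuclear purity cannot be told apart from cross direction, because the INTACT tag came from opposite parents in the crosses. Genomic DNA, as a part or as the whole, stays open as well.

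Cm x L replicate 3 lay toward L x Cm at genes such as MINI3 and TT1. A library of the other cross under a wrong label is argued against over all tested loci, because its lowest correlation with its own cross was 0.931 and its highest with the other 0.883. Over loci with a mean of at least 20 RPKM these were 0.777 and 0.768, against 0.949 between Cm x L replicates 1 and 2. At that level replicate 3 was about as far from its own cross as from the other. Of 18 seed coat markers, 16 were higher there than in both other Cm x L libraries, and the mean log2 level of these markers was highest in replicate 3 of both crosses (4.96, 5.39 and 6.37 in Cm x L replicates 1 to 3 and 5.76, 6.19 and 6.52 in L x Cm replicates 1 to 3). Seed coat RNA alone would lower endosperm transcripts, which is not decided: 16 of 23 type I MADS-box genes but 6 of 16 regulators of endosperm development were higher there than in both others, against 46.3% of loci with a mean of at least 20 RPKM, and cell cycle genes had a mean log2 level of 4.05 against 4.84 and 4.80. Seeds at a stage nearer to that of L x Cm and handling cannot be told apart here: each gives a positive correlation, across genes, of the replicate's difference from 1 Cm x L library with that of L x Cm from the other (0.247 and 0.494 over 8503 genes), and the labels give a single age of 4 days. A partial mixture with L x Cm material gives it too, but would raise every list that was higher in L x Cm. Seed storage genes had mean log2 levels of 2.25, 1.94 and 1.72 in Cm x L replicates 1 to 3 and 2.95 to 3.72 in L x Cm. Annotated pseudogenes had 0.73, 1.30 and 0.56 against 1.70 to 2.49. For these lists the values argue against such a mixture, while type I MADS-box genes lay toward L x Cm.

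Pollen markers were high together in 1 library of each cross. The 4 most abundant, AGP23, VGD1, AGP11 and AGP6, were higher in replicate 2 than in replicate 1 by 2.42 to 2.53 on the log2 scale in Cm x L and by 1.54 to 2.103 in L x Cm, as 1 source would give. RNA of pollen or pollen tubes is therefore a candidate source for these transcripts, although INTACT purification of endosperm nuclei would be expected to remove it. PPME1, TIP1;3 and the sperm genes HTR10 and HAP2 (0 of the 8 markers are in another list) gave −0.07, −0.98, 0.14 and −0.73 in L x Cm and 2.55, 0.08, 1.14 and 0.83 in Cm x L, at low levels. Whether the same source covers them, and a difference of endosperm expression between the crosses, stay open.

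A segment lost or gained in TEmob was tested as a hypothesis. Among runs of 21 neighbouring genes with a mean of at least 20 RPKM, the one around AT1G09500 on chromosome 1 was shifted furthest upward, by 0.61 from the chromosome median, and 1000 shuffles of the gene order gave as large a shift with permutation p = 0.0070. The run shifted furthest downward, by −0.68 around AT1G56418, had permutation p = 0.053. Of the 21 genes of the upward run, 11 lay beyond 0.5 of its shift, the fewest possible because the shift is their median. On the other side of the chromosome median lay 7, so the genes of the run were not shifted alike. The spread of single genes under a true change in copy number was not modelled, and the downward run was not examined in this way. A segment changed in copy number therefore stays open. The split of the 6 libraries by cross called 6662 loci and the other 9 splits at most 1, but 10 splits are too few for a share under 0.05.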
